A study of Mus musculus with 20 samples.

How the data were processed

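Total RNA from 2 mouse myeloma cell lines, 589bm and 595sp, was measured on Illumina mouse bead arrays. Per the labels, the RNA was purified on QIAshredder and RNeasy columns and labelled with biotin through an Illumina TotalPrep amplification kit. Each line had a bortezomib-sensitive and a bortezomib-resistant culture, and each of the 4 cultures was sampled at 0, 2, 8, 16 and 24 h with 1 array per time, which gave 20 arrays.

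The deposited non-normalized table holds 1-colour signal intensity (AVG_Signal) for 45281 probes on the 20 arrays, per the file headers. It has no detection p-values, and its array medians differ, so the values were not normalized between arrays. The deposited series matrix holds intensity on a linear scale in which all 20 columns have the same sorted values, with a column median of 177, so the authors had quantile-normalized them. Each of its columns had a rank correlation of 1 with the non-normalized column of the same title. Its scale, centring and direction are therefore settled, while the software, the scanner settings and the background handling are not given in the sources used here. All deposited sample columns were used.

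The non-normalized intensities were background-corrected by normexp with an offset of 50, taken to log2 and quantile-normalized with limma 3.58.1 in R 4.3.3. With no detection p-values, the brighter 50% of probes by mean log2 signal over all arrays, 22641 probes, were kept. The number of arrays limits the precision, and no depth applies to arrays. Probes were named from the platform annotation, updated through Entrez gene numbers for 34807 probes. There were 34885 probes with 1 gene symbol, 18 with several and 10378 with none, and no gene was named from the last 2 kinds. A gene was represented by the kept probe with the highest mean signal over all arrays used. Of 102 named gene results, 43 came from genes with several kept probes, and in 39 of these all probes had the same sign, while in only 25 all probes passed. Other probes of the same sign lay near 0 for Tomm22, Cd69, Ramp1 and Cd6 within 595sp (0.08, -0.05, -0.16 and 0.31), for Tmsb10 within 589bm (0.31) and for Slc7a3 in the resistant cultures at 24 h (0.14), so these changes rest on part of their probes. The exceptions in sign were Slc7a3 and Espn in the resistant cultures at 16 h, H2ac18 in the resistant cultures at 24 h and Smoc1 in 589bm, where a second probe gave a log2 change of -0.04, 0.03, 0.13 and -0.03. Chromosomes came from a gene table of the assembly GRCm38.p6, used only to group neighbouring genes.

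Arrays were grouped by title. On the 5 arrays titled 595spVR the characteristics disagree with the title on sensitivity and time, while source name and description give the same name as the title. As the pairing comes from the cell line, the culture was kept as a block in the model. Each of the 19 arrays with signal correlated best with another array of its own culture, which is the check of that pairing.

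All comparisons used limma (lmFit, and eBayes with an intensity trend) with Benjamini-Hochberg adjustment, and a probe passed at an adjusted p under 0.05. Responses to the drug were contrasts against the 0 h arrays of the same cultures in a fit of culture plus sensitivity by time, and the difference of the responses was tested as an interaction. This fit left 8 residual degrees of freedom over 20 arrays and 7 over 19. Resistant and sensitive cultures were compared at 0 h (4 arrays, line as a term, 1 residual degree of freedom), as means over the times (4 culture means), and within each line with time as a term. The p-values of the responses treat the 2 lines as replicates and rest on a single 0 h array per culture. Those within a line measure the spread over the times of 1 pair of cultures, not between cultures. Those of the later test of whether the lines differed likewise measure the spread over the times of 4 single cultures.

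Gene groups were 30 lists with 600 genes, of which 544 had a named probe and 472 were tested with 19 arrays. Each list was tested with camera at a preset correlation of 0.01, adjusted over all lists and contrasts of a family (120 tests for each response, 150 for the response differences), with an estimated correlation beside it, and with fry. Counts of members are given over all genes tested and adjusted over the list alone. The samples, designs, lists, alternatives and the rule for named genes were fixed before the data were examined. By that rule, genes had to pass and move the same way in both lines. For each response the 4 largest rises and 3 largest falls were named. For the mean response difference and each comparison of resistant with sensitive cultures, the 12 largest rises and 12 largest falls were named, or the 4 genes with the smallest p where none passed. From a list, up to 4 passing members with the largest change were named, or the largest where none passed, and 15 measured stress, survival and plasma cell genes were tested in every comparison.

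The alternatives were no background correction, median scaling, no filter or a stricter filter (the brighter 25%), the series matrix values, no replicate block, a random block for culture, the 595spVR arrays left out or regrouped, other arrays sharing the spread, fry or an estimated correlation for lists, and each array left out in turn. After the data were seen, fits without the near-blank 589bm resistant 2 h array (19 arrays) were added, alone and combined with the series matrix, median scaling, the 595spVR arrays left out, or each other array left out, together with the test of whether the lines differed.

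The fits were tested on simulated log2 signals of 22641 probes with noise drawn for each probe on its own. Background correction, normalization and the filter were not part of this test. For the sensitive 16 h response in 19 arrays, 13.4%, 80.6% and 100% of genes changed by a log2 of 0.5, 1 and 2 were recovered, and for the difference of the 16 h responses 1.49%, 28.4% and 98.5%. With 1 blank array among 20, the recovered shares for the sensitive 16 h response were 0%, 1.49% and 28.8%. For the comparison within 595sp, they were 44.8%, 100% and 100%. Unchanged probes called numbered 9 for the sensitive 16 h response and 2 for the difference with 19 arrays, 0 for each with the blank array, and 9 within 595sp.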

Results

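Gene expression was measured in 2 mouse multiple myeloma cell lines, 589bm and 595sp, derived per the labels from Bcl-XL/Myc double transgenic mice. Each line was present as a culture sensitive to bortezomib, a proteasome inhibitor used against multiple myeloma, and as a resistant culture. The 4 cultures were sampled at 0 h and after 2, 8, 16 and 24 h of 33 nM bortezomib, with 1 array each. This gave 20 arrays in 10 groups of 2 arrays, with the 2 lines as the replicates of each group, and their number limits the precision.

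The 589bm resistant 2 h array carried almost no probe signal. Its mean signal was 140 and 0.144% of its probes exceeded 2 times its median, against 13.4% to 20.3% on the other 19 arrays. Its median correlation with the other arrays was 0.00846, while the lowest median correlation among the others was 0.938. Counts of probes are therefore given for all 20 arrays, as the design was fixed, and for 19 arrays without this array, a fit chosen after the data were seen. Values of genes and lists come from the 19 arrays unless stated. The 5 arrays titled 595spVR have characteristics that disagree with their titles, and each had another of these 5 as its nearest array.

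**Figure D1:**
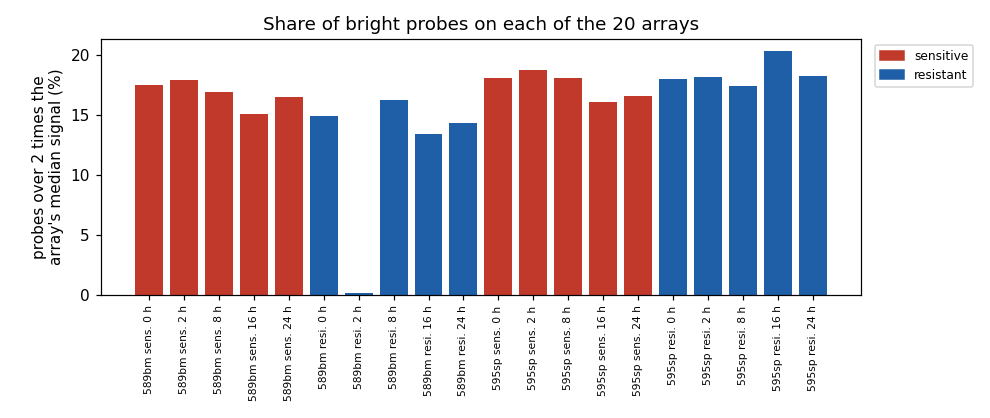
Bars give the share of probes, in percent, with a signal over 2 times the array's median on each of the 20 arrays (red, sensitive cultures; blue, resistant cultures). The 589bm resistant 2 h array stands at 0.144%, and the other arrays at 13.4% to 20.3%.

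The sensitive cultures were compared with their own 0 h arrays, to ask what changed under the drug in cells that had not become resistant to it. No untreated array was taken after 0 h, so here and in the resistant cultures an effect of the drug cannot be told from one of time in culture. At 2 h no gene passed. The nearest was Ankrd37, a gene induced by hypoxia, with a log2 change of -1.37 (SE 0.20, adjusted p = 0.0859 by limma, below 0 in both lines). The next by p were Hnrnpdl, an RNA-binding protein, at 0.84, Ipo7, a nuclear import receptor, at 0.86 and Impact, a regulator of translation, at 0.78, each with an adjusted p of 1. In limma 0 of 22641 probes passed with 20 and with 19 arrays, and 52 and 594 had an unadjusted p under 0.05.

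At 8 h the largest rises in the sensitive cultures were of stress genes, and each gene given here as rising or falling moved the same way in both lines. Hspa1a, an inducible cytosolic chaperone of the Hsp70 family, rose by a log2 of 4.10 (SE 0.37, adjusted p = 9.19e-06). Trib3, a pseudokinase induced by the integrated stress response, rose by 4.01 (SE 0.32, adjusted p = 3.25e-06), Chac1, an enzyme that degrades glutathione, by 3.27 (SE 0.40) and Nupr1, a stress-induced nuclear protein, by 3.18 (SE 0.24). The largest falls were of Ankrd37 at -1.99 (SE 0.20), Cnp, an enzyme abundant in myelin, at -1.45 (SE 0.27, adjusted p = 0.00842) and Bcl11a, a transcription factor of B cell development, at -1.36 (SE 0.24, adjusted p = 0.00502). With 19 arrays 437 probes passed, 268 higher and 169 lower. Counted by the probe that represents each gene, 302 of 11802 genes passed. With 20 arrays 5 passed, all higher, among them Hspa1a, Trib3, Nupr1 and Ddit3, at log2 changes of 3.91, 3.82, 3.03 and 3.01. Median scaling of the 19 arrays called 102, 67 higher and 35 lower. Without the 589bm sensitive 0 h, 595sp sensitive 0 h or 595sp sensitive 8 h array, 86, 169 and 108 probes passed, and Cnp and Bcl11a each missed the threshold in 2 of these 19 fits.

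At 16 h Hspa1a again had the largest rise in the sensitive cultures. It rose by 5.22 (SE 0.37, adjusted p = 6.55e-07), Hspa1b, its near-identical paralog, by 3.98 (SE 0.43, adjusted p = 3.02e-05) and Hspb1, a small heat shock protein, by 3.28 (SE 0.35). Probes may not tell Hspa1a and Hspa1b apart. Trib3 rose by 3.84 (SE 0.32). Ankrd37 fell by 2.38 (SE 0.20), Gcat, a mitochondrial enzyme of threonine breakdown, by 2.11 (SE 0.33) and Cnp by 1.97 (SE 0.27). With 19 arrays 1958 probes passed, 1022 higher and 936 lower, and 1247 genes counted by the probe that represents each gene. With 20 arrays 11 passed, 9 of them higher, with Hspa1a at 4.98 and Ankrd37 at -2.26. Median scaling in place of quantile normalization placed the median of all probes at -0.15 and split the calls into 156 higher and 1136 lower. Without the 589bm sensitive 0 h, 589bm sensitive 16 h or 595sp sensitive 0 h array, 460, 560 and 922 probes passed.

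At 24 h Hspa1a had risen by 5.23 (SE 0.37, adjusted p = 3.44e-07), by 6.24 in 589bm and 4.23 in 595sp. Hspb1 and Trib3 rose by 4.09 each (SE 0.35 and 0.32) and Hspa1b by 3.82 (SE 0.43). Ankrd37 fell by 2.60 (SE 0.20), Gcat by 2.33 (SE 0.33) and H2-Aa, a chain of MHC class II, by 2.28 (SE 0.36, adjusted p = 0.000646). With 19 arrays 2730 probes passed, 1442 higher and 1288 lower, of which 2729 moved the same way in both lines. The spread in this fit is the disagreement between the lines, so the calls favour probes on which the lines agree. Counted by the probe that represents each gene, 1709 genes passed. With 20 arrays 13 passed, 12 of them higher, with Hspa1a at 4.99 and Hspb1 at 3.91. Under median scaling the median of all probes lay at -0.10 and the calls split into 297 higher and 1302 lower. Without the 589bm sensitive 0 h, 589bm sensitive 24 h, 595sp sensitive 0 h or 595sp sensitive 24 h array, 969, 1399, 1270 and 1040 probes passed.

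Targets of ATF4, the transcription factor of the integrated stress response, rose together in the sensitive cultures. Of 26 tested members, 17, 15 and 14 rose at 8, 16 and 24 h, and 24, 20 and 20 did so when adjusted over the list alone, with 1 lower at 24 h. Ddit3, which encodes the CHOP transcription factor, rose by 3.16, 3.20 and 3.41 at these times (SE 0.26), and Atf3 by 3.45 at 24 h (SE 0.28). The medians were 1.26, 0.99 and 1.02, and camera gave adjusted p-values of 5.68e-38, 7.17e-18 and 3.19e-13 (adjusted p = 0.0591, 0.118 and 0.122 with an estimated correlation). Of 21 cytosolic heat shock genes, 9, 10 and 10 rose (12, 11 and 10 adjusted over the list alone), among them Bag3, a co-chaperone, by 2.61, 3.02 and 3.08. The medians were 0.64, 0.48 and 0.60, with camera adjusted p-values of 1.16e-12, 4.16e-07 and 4.59e-05 (adjusted p = 0.123, 0.228 and 0.306 with an estimated correlation).

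Subunits of the proteasome, the complex that bortezomib inhibits, rose as well. Of 31 tested members, 6, 14 and 17 rose at 8, 16 and 24 h (14, 19 and 20 adjusted over the list alone, with 1 lower at 16 and at 24 h). Psmd4, a ubiquitin receptor of the regulatory particle, rose by 1.10, 1.57 and 1.63 (SE 0.22) and Psmc3, an ATPase of that particle, by 1.11, 1.37 and 1.41 (SE 0.19). The medians were 0.48, 0.67 and 0.64, with camera adjusted p-values of 1.59e-11, 4.94e-10 and 1.45e-08 (adjusted p = 0.118, 0.123 and 0.151 with an estimated correlation). Psmb5, the catalytic subunit that binds bortezomib, had log2 changes of -0.01, -0.29 and -0.22, and none passed. Nfe2l1, which encodes a transcription factor of proteasome genes, rose by 0.97, 0.88 and 0.99 (SE 0.21). The immunoproteasome list held 3 of 7 members lower at 24 h (3 adjusted over the list alone), Psmb8 at -1.08, Psmb9 at -0.84 and Psmb10 at -0.59, with a camera adjusted p of 0.0416 (adjusted p = 0.370 with an estimated correlation).

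Some genes of other protein quality control groups rose at 24 h, and of these lists only autophagy and NRF2 were called. Of 19 autophagy and lysosome genes 5 rose (6 adjusted over the list alone), led by Sqstm1, an autophagy receptor, at 3.10 (SE 0.21) and Gabarapl1 at 2.42 (SE 0.19), with a camera adjusted p of 0.00336 (adjusted p = 0.118 with an estimated correlation). Of 13 ubiquitin genes 4 rose (4 adjusted over the list alone), Zfand2a at 2.65, Ufd1 at 1.59, Nploc4 at 1.58 and Nfe2l1 at 0.99, while the list's median was -0.07 and its test pointed up (adjusted p = 0.128). Of 24 ER chaperone and ERAD genes 3 rose and 1 fell (4 and 1 adjusted over the list alone), with Herpud1 at 1.05 and Sec61b at -0.78, and the list's median of 0.07 (adjusted p = 0.538) turned to -0.19 under median scaling. Of 21 NRF2 targets 5 rose (5 adjusted over the list alone), with Mafg at 1.77 and Gclm, a subunit of the glutathione-making enzyme, at 1.03, and a camera adjusted p of 0.0356 (adjusted p = 0.327 with an estimated correlation). Hmox1 at 0.56, Txnrd1 at -0.38 and Xbp1 at 0.70 did not pass. None of 3 metallothionein genes passed (0 adjusted over the list alone, median -0.01, adjusted p = 0.807).

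Among genes of growth arrest and cell death, 5 of 17 p53 targets rose and 1 fell at 24 h (5 and 2 adjusted over the list alone), and the list's median of 0.11 (adjusted p = 0.180) turned to -0.04 under median scaling. Gadd45a rose most (SE 0.20), having reached 2.42 at 16 h, and Cdkn1a, the inhibitor p21, rose by 0.97 (SE 0.25). In the BCL2 family of 14, the pro-death genes Pmaip1 and Bbc3 rose by 1.40 and 0.93, and Bmf, also a pro-death gene, fell by 1.15 (2 and 1 adjusted over the list alone, median 0.26, adjusted p = 0.252). Bcl2l1, which encodes Bcl-XL, had a change of 0.24 that did not pass. Of 15 immediate early genes 5 rose (5 and 1 lower adjusted over the list alone), with Klf6 at 2.62 and Dusp1 at 2.05, and a camera adjusted p of 0.00471 (adjusted p = 0.215 with an estimated correlation). Of 18 NF-kB targets 3 rose (3 adjusted over the list alone), Cd40 at 1.52, Nfkbiz at 0.90 and Relb at 0.81 (adjusted p = 0.0694). Of 17 interferon response genes 3 rose, Rsad2 at 0.79, Oasl1 at 0.76 and Irf9 at 0.66, and Ifi27l2a fell by 1.42 (6 and 1 adjusted over the list alone, adjusted p = 0.067).

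Some genes of growth and energy metabolism fell in the sensitive cultures. At 24 h 8 of 23 ribosome biogenesis and MYC genes were lower (13 adjusted over the list alone), with Tfrc, the transferrin receptor, at -1.79 (SE 0.19), Pes1 at -1.53 (SE 0.26) and Srm at -1.15 (SE 0.21), and a camera adjusted p of 2.99e-06 (adjusted p = 0.0676 with an estimated correlation). Myc itself had changes of -0.22, -0.59 and -0.50 at 8, 16 and 24 h, which did not pass (adjusted p = 0.0508 at 16 h). Of 13 glycolysis genes 5 fell (7 adjusted over the list alone), with Pdk1 at -1.62 and Ldha, lactate dehydrogenase, at -1.29 (camera adjusted p = 0.00304; adjusted p = 0.263 with an estimated correlation). Of 26 oxidative phosphorylation genes 6 fell (7 adjusted over the list alone), with Atp5a1 at -1.82 and Ndufb5 at -1.41 (camera adjusted p = 0.00124; adjusted p = 0.215 with an estimated correlation). Of 24 S phase genes 6 fell (10 lower and 1 higher adjusted over the list alone), with Rrm2, a ribonucleotide reductase subunit, at -1.09 (camera adjusted p = 0.0021; adjusted p = 0.215 with an estimated correlation). Of 21 mitosis genes 3 fell (5 adjusted over the list alone), Kif23 at -1.01, Aurkb at -0.98 and Nusap1 at -0.95 (camera adjusted p = 0.0416; adjusted p = 0.327 with an estimated correlation). Cyp51 fell by 0.83 among 17 cholesterol synthesis genes (0 adjusted over the list alone, adjusted p = 0.227), and none of 20 cytosolic ribosomal protein genes passed (0 adjusted over the list alone), with a median of 0.03 that turned to -0.36 under median scaling (adjusted p = 0.833 and 0.0705).

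Some genes of B cell identity and antigen presentation also fell. At 24 h 7 of 20 B cell genes were lower (8 lower and 1 higher adjusted over the list alone), with Cd22, an inhibitory coreceptor, and Vpreb3 at -1.51 each and Cd52 at -1.32 (camera adjusted p = 0.00155; adjusted p = 0.118 with an estimated correlation). Of 10 MHC class II genes 6 fell (7 adjusted over the list alone), with H2-DMa at -1.18 and H2-Ab1 at -0.97 beside H2-Aa, a list median of -0.94 and a camera adjusted p of 3.97e-05 (adjusted p = 0.296 with an estimated correlation). Of 7 MHC class I genes H2-D1 rose by 0.57 (1 adjusted over the list alone), and the list's median of 0.08 turned to -0.17 under median scaling. Of 17 plasma cell genes 3 fell (3 adjusted over the list alone), Tnfrsf13b at -0.85, Fkbp11 at -0.78 and Txndc5 at -0.62 (adjusted p = 0.0772), while Prdm1, Irf4 and Sdc1 at -0.18, -0.24 and -0.13 did not pass. Of 8 ABC transporters Abcc5 rose by 1.35 (1 adjusted over the list alone), and the list's median of 0.05 turned to -0.22 under median scaling. Abcb1b, a P-glycoprotein gene, had a change of 0.05 that did not pass. Among markers of other cells, 2 of 8 T cell genes fell, Cd3g at -1.76 and Cd2 at -0.81 (2 adjusted over the list alone), Mpeg1 of 9 macrophage genes fell by 2.25 (1 lower and 1 higher adjusted over the list alone), Hbb-bt of 5 erythroid genes fell by 1.35 (1 adjusted over the list alone), and 0 of 6 stromal genes passed (0 adjusted over the list alone). The adjusted p-values of these 4 lists were 0.0754, 0.833, 0.431 and 0.594.

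Some members of these groups had already passed at 8 h, and no list was tested between times. Of the ER chaperone and ERAD genes, Herpud1, a gene induced by the unfolded protein response, rose by 1.07 at 8 h, when the list had a median of 0.32 (1 member higher, 2 adjusted over the list alone) and a camera adjusted p of 0.000707 (adjusted p = 0.306 with an estimated correlation). Of the ubiquitin genes, 4 rose at 8 h (5 adjusted over the list alone), with Zfand2a at 2.22 and Ufd1 at 1.35, a median of 0.24 and a camera adjusted p of 0.00318 (adjusted p = 0.218 with an estimated correlation). Pdk1, an inhibitor of pyruvate dehydrogenase, fell by 0.97 at 8 h among the glycolysis genes (2 lower, 5 adjusted over the list alone; camera adjusted p = 0.000802; adjusted p = 0.215 with an estimated correlation), and Cd22 by 1.29 among the B cell genes (3 lower, 4 adjusted over the list alone; camera adjusted p = 0.00514; adjusted p = 0.123 with an estimated correlation).

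**Figure D2:**
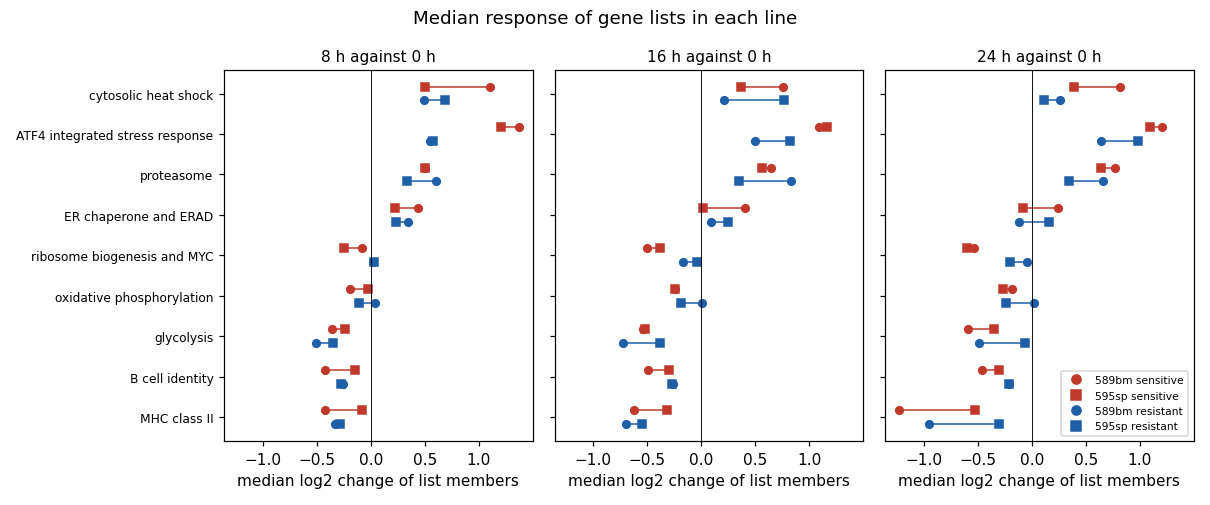
Points give the median log2 change of the tested members of 9 gene lists against 0 h at 8, 16 and 24 h, from 19 arrays (circles, 589bm; squares, 595sp; red, sensitive; blue, resistant), with a line joining the 2 lines. The ATF4 list lies highest in the sensitive cultures at each time, the proteasome list lies at similar heights in both kinds of culture, and the medians of the ER chaperone list in the sensitive cultures turn below 0 at 16 and 24 h under median scaling.

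The resistant cultures were followed in the same way, to ask what still changed under the drug once the cells were resistant. At 2 h no gene passed. Ankrd37 was at -1.31, Nrp2, a semaphorin coreceptor, at 0.82, Adam7 at 0.82 and Zbtb7b, a transcription factor of T cell lineage choice, at -0.76, each with an adjusted p of 1. In limma 0 probes passed with 20 and with 19 arrays, and 8362 and 500 had an unadjusted p under 0.05. With 19 arrays this comparison rests on 595sp alone.

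At 8 h Chac1 rose in the resistant cultures by 2.24 (SE 0.40, adjusted p = 0.0296), Trib3 by 1.95 (SE 0.32, adjusted p = 0.0187), Glipr1 by 1.59 (SE 0.26, adjusted p = 0.0178) and Bag3 by 1.52 (SE 0.19, adjusted p = 0.0029). Ankrd37 fell by 1.41 (SE 0.20), Dbp, a circadian transcription factor, by 1.32 (SE 0.17) and Selplg, the ligand of P-selectin, by less (SE 0.19, adjusted p = 0.0178). With 19 arrays 39 probes passed, 26 higher and 13 lower, and 24 genes counted by the probe that represents each gene. With 20 arrays 0 passed and 247 had an unadjusted p under 0.05 in limma. All 7 named genes kept their sign but missed the threshold without a resistant 0 h or resistant 8 h array of either line, fits in which 0 or 1 probes passed, and 71 probes passed without the 589bm or the 595sp sensitive 16 h array. Median scaling of the 19 arrays called 5, 3 higher and 2 lower.

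At 16 h Trib3 rose by 2.44 (SE 0.32, adjusted p = 0.00212), Chac1 by 2.43 (SE 0.40), Slc7a3, a transporter of cationic amino acids, by 2.20 (SE 0.30) and Nupr1 by 1.84 (SE 0.24). Macrod1, an ADP-ribose hydrolase, fell by 1.59 (SE 0.24), Espn, an actin-bundling protein, by 1.53 (SE 0.26) and Fndc10 by 1.52 (SE 0.20). With 19 arrays 247 probes passed, 126 higher and 121 lower, and 157 genes counted by the probe that represents each gene. With 20 arrays 0 passed and 415 had an unadjusted p under 0.05 in limma, and under median scaling of the 19 arrays 14 were higher and 5 lower. Without the 589bm resistant 0, 8 or 16 h array 23, 158 and 8 probes passed, without the 595sp resistant 0, 8 or 16 h array 33, 157 and 54, and each of the 7 named genes missed the threshold in at least 1 of these fits.

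At 24 h Trib3 had risen by 2.70 (SE 0.32, adjusted p = 0.000673), Chac1 by 2.62 (SE 0.40), Slc7a3 by 2.57 (SE 0.30) and Nupr1 by 2.20 (SE 0.24). H2ac18 and H2ac19, histone H2A genes, fell by 1.76 (SE 0.22) and 1.71 (SE 0.24), and Rsph1, a protein of ciliary radial spokes, by 1.63 (SE 0.28, adjusted p = 0.00731). With 19 arrays 239 probes passed, 139 higher and 100 lower, and 167 genes counted by the probe that represents each gene. Under median scaling of the 19 arrays 31 probes passed, 19 higher and 12 lower. With 20 arrays 0 passed and 415 had an unadjusted p under 0.05 in limma. Without the 589bm resistant 0, 8 or 24 h array 28, 158 and 29 probes passed, and without the 595sp resistant 0, 8 or 24 h array 54, 159 and 22. Chac1, H2ac19 and Rsph1 missed the threshold without the 595sp resistant 0 h or 24 h array, and Rsph1 also without the 589bm resistant 24 h array.

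By group, ATF4 targets rose in the resistant cultures in 4, 8 and 10 of 26 members at 8, 16 and 24 h (13, 18 and 20 adjusted over the list alone), with medians of 0.63, 0.72 and 0.78. Camera gave adjusted p-values of 1.72e-14, 2.89e-19 and 1.18e-22 (adjusted p = 0.0913, 0.0759 and 0.0759 with an estimated correlation). Ddit3 was at 0.83, 1.38 and 1.69 and passed at 16 and 24 h, and Atf5 rose by 2.04 at 24 h. Proteasome genes rose in 1, 9 and 7 of 31 members (13, 20 and 14 adjusted over the list alone, with 1 lower at 16 h), with medians of 0.47, 0.55 and 0.52, among them Psmc5 at 0.97 at 8 h, Psmd2 at 1.40 at 16 h and Psmb6 at 0.92 at 24 h. The camera adjusted p-values were 5.61e-16, 5.71e-16 and 3.48e-13 (adjusted p = 0.0759 each with an estimated correlation). Of 21 heat shock genes 1, 2 and 2 rose (7, 7 and 6 adjusted over the list alone, with 1 lower at 16 and at 24 h). Hspa1a was at 1.52, 1.78 and 1.99 and passed at 16 and 24 h (adjusted p = 0.0281 and 0.0129), and Hspa1b at 0.68, 0.80 and 0.73 did not pass. The heat shock list had camera adjusted p-values of 5.49e-12, 1.34e-05 and 0.00188 (adjusted p = 0.107, 0.276 and 0.427 with an estimated correlation).

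At 24 h in the resistant cultures, Sqstm1 rose by 1.89 and Gabarapl1 by 1.38, the passing 2 of 19 autophagy genes (5 adjusted over the list alone; camera adjusted p = 0.000282; adjusted p = 0.0759 with an estimated correlation). Klf6 rose by 1.59, Gadd45a by 1.17, Nfe2l1 by 0.92 and Zfand2a by 1.12. Ccne2, an S phase cyclin, fell by 1.32 and Tk1 by 0.89 among 24 S phase genes (7 lower adjusted over the list alone), with a list median of -0.33 and a camera adjusted p of 1.21e-07 (adjusted p = 0.0759 with an estimated correlation). Cdc20 rose by 0.88 among 21 mitosis genes (1 adjusted over the list alone, adjusted p = 0.698). Ldha fell by 0.94 and Pfkl by 0.86 among 13 glycolysis genes (4 adjusted over the list alone; camera adjusted p = 0.000413; adjusted p = 0.157 with an estimated correlation), and Tfrc fell by 0.97. Cd72, a B cell coreceptor, fell by 0.98, and Cd3g by 1.21. Of 10 MHC class II genes 0 passed over all genes tested and 7 were lower adjusted over the list alone, with a median of -0.65 and a camera adjusted p of 1.23e-05 (adjusted p = 0.229 with an estimated correlation).

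Some further lists were called by camera in the resistant cultures at 24 h with few or no members passing, and none of them with an estimated correlation. NRF2 targets had a median of 0.29 with 0 of 21 passing (4 adjusted over the list alone; camera adjusted p = 0.00026; adjusted p = 0.124 with an estimated correlation), while at 16 h Gclm and Mafg had passed at 0.95 and 0.69. Immediate early genes, with Klf6 and Ier3 passing, had a camera adjusted p of 0.00188 (4 adjusted over the list alone; adjusted p = 0.126 with an estimated correlation), and p53 targets, with Gadd45a passing, 0.0481 (3 higher and 1 lower adjusted over the list alone; adjusted p = 0.159 with an estimated correlation). The B cell list, with Cd72 passing, had a camera adjusted p of 0.0143 (1 adjusted over the list alone; adjusted p = 0.120 with an estimated correlation), and the ribosome biogenesis and MYC list, with Tfrc passing, 0.0325 (1 adjusted over the list alone; adjusted p = 0.157 with an estimated correlation). Psmb8 fell by 0.81 and Herpud1 rose by 0.77, but their lists were not called (adjusted p = 0.0837 and 0.771), nor was the ubiquitin list (adjusted p = 0.256). Psmb5 at 0.26, Myc at -0.34, Xbp1 at 0.63, Pmaip1 at 0.60 and Abcb1b at 0.43 did not pass.

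**Figure D3:**
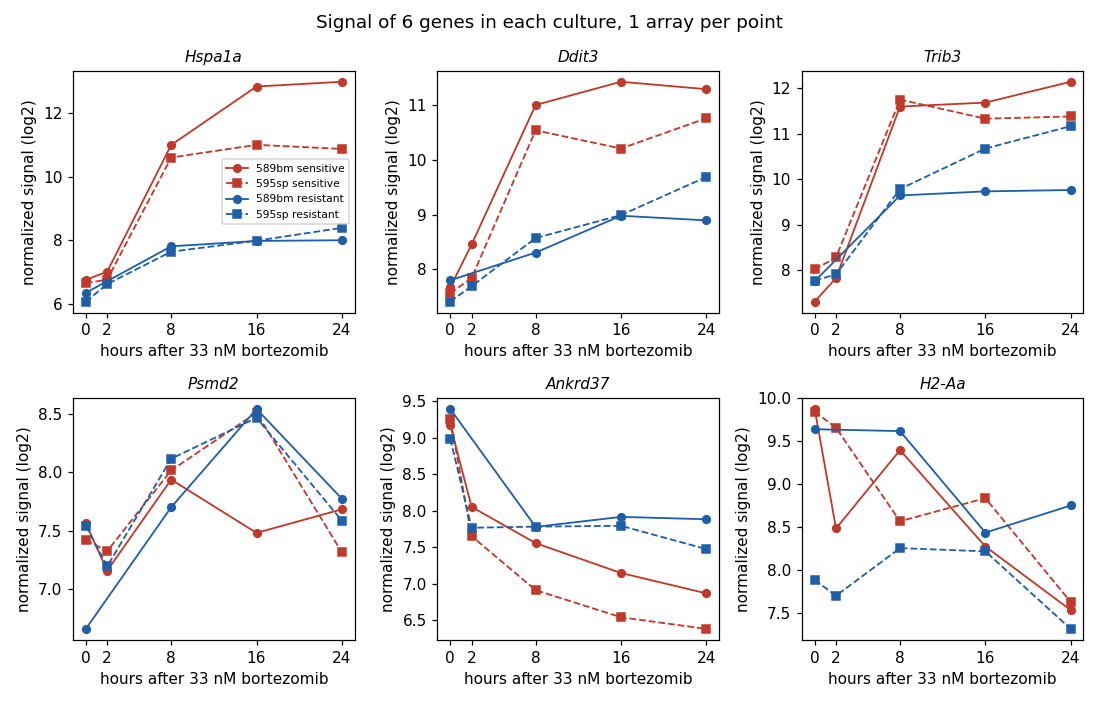
Lines give the quantile-normalized log2 signal of 6 genes on 19 arrays against hours of 33 nM bortezomib, 1 array per point, for the 4 cultures (red, sensitive; blue, resistant; circles, 589bm; squares, 595sp). Hspa1a and Ddit3 rise further in the sensitive than in the resistant cultures of both lines, and Ankrd37 is lower from 8 h on than at 0 h in all 4.

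The difference of the responses asked which genes reacted less, or more, once the cells were resistant. Over the mean of 8, 16 and 24 h, the response of Hspa1a was smaller in the resistant cultures by a log2 of -3.09 (SE 0.43, adjusted p = 0.00879), that of Hspa1b by -2.83 (SE 0.50, adjusted p = 0.0413) and that of Hspb1 by -2.31 (SE 0.41, adjusted p = 0.0413). Snhg12 and Snhg5, host genes of small nucleolar RNAs, differed by -2.21 (SE 0.24, adjusted p = 0.000995) and -1.64 (SE 0.27, adjusted p = 0.0228). Ddit3 differed by -1.96 (SE 0.29, adjusted p = 0.0139) and Bag3 by -1.54 (SE 0.21, adjusted p = 0.00879). Gadd45a was at -1.43 (SE 0.24), Cebpb, a transcription factor induced by stress, at -1.44 (SE 0.25) and Ppp1r15a, a phosphatase subunit that ends the translation block of the stress response, at -1.41 (SE 0.25). The unannotated transcripts 2410006H16Rik and 5430416N02Rik were at -1.82 and -1.59. All 12 lay below 0 in both lines, where the rule for naming required a shared sign. Their sensitive responses were rises, such as 4.85 for Hspa1a against 1.76 in the resistant cultures.

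With 19 arrays 16 probes passed in the mean difference, 1 higher and 15 lower. Counted by the probe that represents each gene, 13 genes passed, all lower. With 20 arrays 0 passed and 375 had an unadjusted p under 0.05 in limma, with Hspa1a at -2.94. At single times, where leaving out 1 array gave 0 to 50 probes at 16 h (the 50, without the 595sp sensitive 16 h array, being 35 higher and 15 lower) and 0 to 19 at 24 h, 0, 0, 8 and 6 probes passed at 2, 8, 16 and 24 h with 19 arrays (224, 1229, 1960 and 2500 at an unadjusted p under 0.05), and 0 each with 20 arrays (599, 157, 256 and 364). Median scaling of the 19 arrays moved the median of all probes to 0.21 at 16 h, 0.12 at 24 h and 0.13 in the mean, and split the calls into 2 higher and 5 lower in the mean and 2 higher and 3 lower at 16 h, against 2 and 6, while 0 probes passed at 24 h. In the mean difference 0 probes passed without the 589bm resistant 0 h array, 1 without the 589bm sensitive 0 h, 4 without the 595sp resistant 0 h, 8 without the 589bm resistant 24 h or 595sp resistant 8 h, 9 without the 595sp resistant 16 h, 10 without the 589bm resistant 8 or 16 h, 38 (11 higher, 27 lower) without the 595sp sensitive 16 h and 84 (47 higher, 37 lower) without the 589bm sensitive 8 h array, so in the last of these most calls were higher. None of the 12 genes passed in all 19 of these fits, and all 12 kept their sign.

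Among the lists, 4 of 21 heat shock genes differed in the mean response (6 adjusted over the list alone), with a camera adjusted p of 0.00291 (adjusted p = 0.833 with an estimated correlation), and the list's median of -0.10 turned to 0.07 under median scaling. Of 26 ATF4 targets 3 were lower (8 adjusted over the list alone), with a median of -0.33 and a camera adjusted p of 1.95e-05 (adjusted p = 0.674 with an estimated correlation). The mitosis list had a median of 0.19 with 0 members passing (4 higher adjusted over the list alone; camera adjusted p = 0.00165; adjusted p = 0.477 with an estimated correlation), and the ribosome biogenesis and MYC list a median of 0.26 (0 members in either count; camera adjusted p = 0.00495; adjusted p = 0.423 with an estimated correlation). For oxidative phosphorylation 0 members passed (3 higher adjusted over the list alone; camera adjusted p = 0.044; adjusted p = 0.774 with an estimated correlation). The proteasome list had a median difference of -0.12 (adjusted p = 0.763), which turned to 0.32 under median scaling, and the MHC class II list 0.01 (adjusted p = 0.808), so no difference between the responses was called for either. Psmb5, Myc, Bcl2l1, Xbp1 and Abcb1b had differences of 0.62, 0.03, -0.31, -0.41 and 0.42 that did not pass.

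The directions of the responses overlapped, and the sensitive and resistant responses share no control array. Of the probes called in the sensitive cultures at 8, 16 and 24 h, 417 of 437, 1793 of 1958 and 2357 of 2730 had the same sign in the resistant cultures, with slopes of resistant on sensitive changes of 0.473, 0.450 and 0.365 over these probes, which were selected for their sensitive change. Of the 39, 247 and 239 probes called in the resistant cultures, 51.3%, 55.1% and 59.8% had the larger change in the sensitive cultures. Probes called higher in both numbered 23, 96 and 116, against 0.308, 5.69 and 8.85 for independent lists, and probes called lower in both 11, 90 and 72, against 5.69 or fewer. No probe was called in opposite directions at these times.

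The comparison of resistant with sensitive cultures asked what set the resistant cells apart before and during treatment. Only the comparison at 0 h leaves out the treated times. The mean over times and the comparisons within a line take them together with 0 h, so they also hold differences in the response to the drug. At 0 h no gene passed. Those with the smallest p were Cd93, a receptor of the early B lineage, at -2.68 (SE 0.33), Slpi, a protease inhibitor, at -2.40 (SE 0.34), Mpeg1, a pore-forming protein, at -2.31 (SE 0.34) and Tbxa2r, the thromboxane receptor, at 2.01 (SE 0.30), each with an adjusted p of 0.291. Camera placed B cell genes lower (median -0.41, adjusted p = 0.00468), heat shock genes lower (-0.29, 0.0126), interferon response genes higher (0.29, 0.0132) and macrophage genes lower (-0.18, 0.0419), each with 0 members passing (4, 0, 0 and 1 lower adjusted over the list alone) and an adjusted p of 0.884 with an estimated correlation. In limma 0 probes passed with 20 and with 19 arrays, with 1952 and 1903 at an unadjusted p under 0.05, and median scaling of the 19 arrays called 64, 17 higher and 47 lower.

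Over the mean of the times, resistant cultures had Ifitm1, an interferon-induced membrane protein, at 3.13 (SE 0.33, adjusted p = 0.153), S100a11, a calcium-binding protein, at 2.07 and Itgb7, an integrin chain, at 1.98, while Hspa1a was at -2.60 (adjusted p = 0.266 for each of these 3), and none passed. With 20 arrays 22 probes passed, 8 higher and 14 lower. Among them Ifitm1 was higher by 2.45 (SE 0.45, adjusted p = 0.00459), Cd6, a lymphocyte receptor, by 1.83 and Echdc2 by 1.62. Hspa1a was at -2.26, Psmd8, a proteasome subunit, at -2.22 (adjusted p = 0.0498), Cd93 at -2.09, Hspa1b at -1.72, Osr2 at -1.65 and Npw at -1.45. The 589bm part of these 20-array values holds the near-blank array. In 589bm, Psmd8 was at -1.03 with that array and at -0.25 without it, while Hspa1a was at -2.76 and -3.37. Npw was at -0.10 in 595sp. With 19 arrays 0 probes passed and 1358 had an unadjusted p under 0.05 in limma, and median scaling of the 19 arrays called 267, 83 higher and 184 lower. In camera the heat shock list (median -0.50, adjusted p = 2.52e-10) and the ATF4 list (-0.36, 7.46e-06) were lower and the ribosome biogenesis and MYC list (0.28, 0.00625) higher, with 0 members of each passing (5 and 6 lower and 0 adjusted over the list alone; adjusted p = 0.884 each with an estimated correlation). The MHC class I list (-0.43, 0.00249), the B cell list (-0.21, 0.0132) and the macrophage list (-0.19, 0.0132) were lower as well, again with 0 members passing (3, 2 and 1 lower adjusted over the list alone) and 0.884 with an estimated correlation. With all 20 arrays the camera test of the ribosome biogenesis and MYC list pointed the other way.

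Within each line, the genes are ordered here among those that passed and had the same sign in both lines. The size in the other line did not count. Snhg12, Popdc3 and Tmsb10 were at -0.002, -0.02 and 0.04 in 595sp, Lxn was at -0.03 in 589bm, and none passed there. Ifitm1, Itgb7 and S100a11 passed in both lines. Genes of opposite sign are left out, such as Vpreb1 at -5.35 in 595sp and 0.18 in 589bm. In 589bm, Lgals3, a galectin, had the largest rise with a shared sign in the resistant culture, at 2.85 (SE 0.16, adjusted p = 4.04e-08). Ifitm1 at 2.50, Ly6c1, an antigen of plasma cells, at 2.18, Itgb7 at 2.17, Tmsb10 at 2.13 and Cdkn1c, a cell cycle inhibitor, at 1.95 followed, and 1700048O20Rik, S100a11, Smoc1, Zscan12, Vkorc1 and Dkkl1 lay between 1.76 and 1.86. Cox6a2, a subunit of cytochrome oxidase, was the lowest of these at -3.95 (SE 0.13, adjusted p = 8.97e-11), followed by Hspa1a at -3.37, Wwc2 at -3.14, Hspa1b at -2.72 and Npw at -2.68. Osr2 was at -2.64, Nupr1 at -2.51, Tigd2 at -2.38, Armcx2 at -2.24, Popdc3 at -2.02, Snhg12 at -1.97 and H2-Ea at -1.91. Hspa1a, Hspa1b, Npw and H2-Ea lie on chromosome 17, whose genes had a median difference of -0.23 in this line. Ly6c1 and Itgb7 rose on chromosome 15, where the median was -0.24. Psmb5 was lower at -1.13 (SE 0.20, adjusted p = 0.00116), Bcl2l1 at -0.74, Nfe2l1 at -0.75 and Xbp1 higher at 0.55. With 20 arrays these were at -1.50, -2.18, -0.49 and -0.29 and did not pass, so Xbp1 had the opposite sign. With 19 arrays 3893 probes passed, 1913 higher and 1980 lower, and with 20 arrays 0 passed, with 1910 at an unadjusted p under 0.05 in limma. Under median scaling of the 19 arrays 813 were higher and 3573 lower, and 1826 and 1806 probes passed without the 589bm sensitive or resistant 8 h array.

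By group, 10 of 21 heat shock genes were lower in the resistant 589bm culture (13 adjusted over the list alone; camera adjusted p = 7.11e-06), with Hsph1 at -1.90, and 15 of 26 ATF4 targets (17 adjusted over the list alone; camera adjusted p = 2.44e-08), with Atf3 at -1.73. Of 13 glycolysis genes 8 were higher (9 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.000181), with Pfkp at 0.95 and Pfkl at 0.90. Of 17 plasma cell genes 7 were higher (7 adjusted over the list alone; camera adjusted p = 0.0265), with Txndc5 at 1.46 and Fkbp11 at 1.35 beside Ly6c1, and 4 of 17 interferon response genes (4 adjusted over the list alone; camera adjusted p = 0.0368), with Usp18 at 1.14. Of 7 MHC class I genes 2 were lower (3 adjusted over the list alone; camera adjusted p = 0.0419), H2-K1 and, at -0.74, H2-D1. Of 26 oxidative phosphorylation genes 9 were higher and 1 lower (12 and 2 adjusted over the list alone; camera adjusted p = 0.0132), and the list's median of 0.28 turned to -0.02 under median scaling. With an estimated correlation each of these 7 lists had an adjusted p of 0.884. Metallothioneins Mt2 and Mt1 were higher at 0.67 and 0.54, and Thy1, an antigen of T cells, at 1.42.

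Within 595sp, among genes with the same sign in both lines, Reln, an extracellular matrix protein, had the largest rise in the resistant culture, at 4.03 (SE 0.12, adjusted p = 1.34e-09). Ifitm1 at 3.75, Cd6 at 3.19, Echdc2 at 2.85, Tomm22, a subunit of the mitochondrial import pore, at 2.77, Ifi30, a lysosomal thiol reductase, at 2.64 and Slc25a17 at 2.54 followed. Alpl, alkaline phosphatase, was at 2.46, Mfsd2a at 2.45, Cd2, a lymphocyte adhesion molecule, at 2.33, S100a11 at 2.32 and Tcea3 at 2.11. Psmd8 was the lowest of these at -3.58 (SE 0.11, adjusted p = 2.21e-09, from 1 kept probe), followed by Cd93 at -2.97, Lxn at -2.69, AA467197 at -2.54, Dpp4, a membrane peptidase, at -2.50 and Cd69, an activation antigen, at -2.47. Gja1, Mtmr14, Endod1, Klra16, Ramp1 and Ptpn12 lay between -2.29 and -2.12. Echdc2, Alpl, Mfsd2a and Tcea3 lie on chromosome 4, whose genes had a median difference of 0.40 in this line. Reln rose on chromosome 5, where the median was -0.30. Myc was higher at 1.66 (SE 0.10, adjusted p = 7.43e-07), Irf4, a transcription factor of plasma cells, at 1.15, Hmox1 lower at -0.94 and Abcb1b at -0.45. With 20 arrays 4171 probes passed, 2149 higher and 2022 lower, and with 19 arrays 4219, 2168 higher and 2051 lower, while median scaling of the 19 arrays gave 1959 higher and 1052 lower. With 20 arrays, 561 passed when other arrays shared the spread and 0 when the 595spVR arrays were grouped by their characteristics.

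By group, 12 of 23 ribosome biogenesis and MYC genes were higher and 1 lower in the resistant 595sp culture (17 and 1 adjusted over the list alone; camera adjusted p = 7.46e-06), with Srm at 1.48 and Nop2 at -1.39. Of 10 MHC class II genes 8 were lower and 1 higher (9 and 1 adjusted over the list alone; camera adjusted p = 0.000354), with H2-Ob at -1.04 and H2-Aa at -1.03. Of 7 MHC class I genes 6 were lower (6 adjusted over the list alone; camera adjusted p = 0.00361), with H2-K1 at -1.15, and of 7 immunoproteasome genes 4 (4 adjusted over the list alone; camera adjusted p = 0.0139), with Tap2, a peptide transporter, at -1.59. Of 20 B cell genes 9 were lower and 2 higher (11 and 4 adjusted over the list alone; camera adjusted p = 0.0146), with Blk, a B cell kinase, at -2.26 and Bcl6 at -1.64. Of 21 heat shock genes 7 were lower (10 adjusted over the list alone; camera adjusted p = 0.00134), with Fkbp4 at -1.31. Of 9 macrophage genes 6 were lower (7 adjusted over the list alone; camera adjusted p = 0.00177), with Mpeg1 at -1.53 and Csf1r at -1.16. Of 24 ER chaperone and ERAD genes 6 were lower and 1 higher (8 and 1 adjusted over the list alone; camera adjusted p = 0.0265), and of 24 S phase genes 5 were higher and 1 lower (7 and 2 adjusted over the list alone; camera adjusted p = 0.0422). With an estimated correlation each of these 9 lists had an adjusted p of 0.884.

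Most of these differences were not shared by the lines. Across genes, the resistant minus sensitive differences of the lines had a Pearson r of 0.0638 and a Spearman rho of 0.0653, and genes are not independent replicates. Of 11802 genes, 2373 passed in 589bm and 2620 in 595sp. There were 292 higher in both, against 139 for independent lists, and 199 lower in both, against 124. Opposite calls numbered 212 (higher in 589bm) and 148 (higher in 595sp), against 143 and 120. In a test of the difference between the lines, chosen after the data were seen, Cox6a2 (adjusted p = 3.01e-10), Psmd8 (4.24e-08), Reln (1.17e-07) and Tmsb10 (3.44e-07) differed between the lines, while Itgb7, S100a11, Tcea3, Hspa1a and Hspa1b did not pass (0.484, 0.205, 0.209, 0.0795 and 0.148). This test has a single culture per line and sensitivity, so its p-values measure the spread over times, not between cultures.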

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

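The tests in this part, other than the splits of all 10 arrays of each line, were chosen after the results were seen, and the tests of the signal range and of a response scaled down alike replaced earlier versions whose outcomes had been seen.

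A single array stood far from the others. On the 589bm resistant 2 h array, the share of probes over 2 times the median had a Dixon ratio of 0.821 among the 5 arrays of its culture and 0.655 among the 10 resistant arrays. Its median correlation with the other arrays had ratios of 0.980 and 0.980, against critical values of 0.71 for 5 arrays and 0.466 for 10. The ratios of its mean signal (0.580 and 0.372) and of its 95th percentile of signal (0.536 and 0.314) stayed under these values. Chance alone puts about 1 in 20 groups past such a critical value. A failed hybridization or labelling predicts that the other line keeps its signal at the same time, and 18.1% of probes on the 595sp resistant 2 h array exceeded 2 times its median, which fits a failed array. A fall in expression in resistant cells at 2 h predicts a remaining correlation with other arrays, and the highest was 0.0342, which speaks against it. With no second array of that culture at 2 h, a loss of the RNA before labelling could not be told from a failure on the array.

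Several of the genes called for a smaller response in the resistant cultures were stress genes. With 20 arrays 0 probes passed in this difference, and the values here are from 19 arrays. Probes called for the difference of the responses numbered 8 at 16 h, 6 at 24 h and 16 in the mean of 8, 16 and 24 h. The genes in the mean were Hspa1a (-3.09), Hspa1b (-2.83), Hspb1 (-2.31), Snhg12 (-2.21), Ddit3 (-1.96), 2410006H16Rik (-1.82), Snhg5 (-1.64), 5430416N02Rik (-1.59), Bag3 (-1.54), Cebpb (-1.44), Gadd45a (-1.43), Ppp1r15a (-1.41) and Ypel5 (-1.39), the last of them named after its value was seen. Without the 589bm sensitive 8 h array the calls in the mean were 47 higher and 37 lower, so the direction of the calls rested on that array too.

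A narrower signal range on the resistant arrays predicts a lower 95th percentile of signal in both lines. The resistant to sensitive ratio of the non-normalized signal was 0.922 in 589bm and 1.44 in 595sp, so the range before normalization was not narrower in 595sp. Range may play a part in 589bm. As the tested values were quantile-normalized, the ratio cannot settle an effect of range on them. A higher start at 0 h in the resistant cultures had a median of 0.19 over the 13 genes, with 8 above 0, so it does not account for the differences of the 13 genes as a set, but for 2410006H16Rik and Cebpb, which started highest (0.89 for Cebpb, against a difference of -1.44), it remains open as part of the cause. Whether the whole response was scaled down alike could not be told. The ratio of resistant to sensitive median responses was 0.954 for the proteasome list (95% interval 0.695 to 1.52), 0.692 for the ATF4 list (0.431 to 0.937) and 0.738 for the heat shock list (0.282 to 2.44). Of their members, 20 of 31, 21 of 26 and 13 of 21 had the smaller change in the resistant cultures. The intervals come from resampling list members, so they hold no spread between lines or cultures.

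The lines differed in what set their resistant cultures apart, with 4265 probes called in the test of the line by resistance interaction with 19 arrays. With a single culture per line and sensitivity, its p-values measure the spread over times, not between cultures. If the lines had taken up the same changes, their differences would correlate across genes, and Pearson r was 0.0638. Among other splits of the arrays of 595sp into groups of the same sizes, chance can be excluded only for how these arrays group, with 4171 probes for the real split, the only 1 of 100 that called as many, and 131 for the highest other. The other splits mix arrays of the same cultures, so a chance difference between the cultures, unrelated to resistance, is not excluded in either line. For 589bm with all 10 arrays the splits decide nothing, since the real split called 0 probes and 100 of 100 splits therefore called as many. The highest other called 13940, which points to a structure of the arrays, among them the near-blank array. With the 8 arrays of 589bm that had a partner at the same time, only 1 of 32 splits, the real split with 3899 probes, called as many, and the highest other called 0.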

How the results depend on the processing

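Values here start from all 20 arrays, as the design was fixed. No gene whose value was followed through the settings reversed its sign, but not every gene printed was followed. Within 589bm, Xbp1 was at -0.29 with 20 arrays and at 0.55 with 19. In the resistant response at 2 h, Irf4, Myc and Hspa1b were at -0.70, -2.08 and 0.02 with 20 arrays and at 0.21, 0.01 and -0.18 with 19, and none of these passed. The main counts were 0, 5, 11 and 13 for the sensitive response at 2, 8, 16 and 24 h, 0 for each resistant response and response difference, 0 for resistant against sensitive at 0 h, 22 for the mean over times, 0 within 589bm and 4171 within 595sp. Counts are probes in limma, and in parentheses higher and lower. Unless a reason is given, the cause was not tested. Signal over background was lost on the near-blank array, which limits the resistant 2 h comparison.

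For the gene lists, 107 list results passed in camera (48 higher, 59 lower), 19 in fry (7, 12), 0 with an estimated correlation (smallest adjusted p 0.0787) and 0 with the near-blank array left out and an estimated correlation (0.0591).

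With no replicate block the sensitive response had 0 at 8 h and 2 (2, 0) at 16 h, the mean over times 0 and 589bm 119 (10, 109). With no background correction the mean over times had 0.

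With median scaling the sensitive response had 78 (32, 46) at 8 h, 303 (56, 247) at 16 h and 566 (137, 429) at 24 h. The resistant response had 43 (0, 43) at 2 h, 3 (1, 2) at 8 h, 10 (8, 2) at 16 h and 21 (14, 7) at 24 h. The response difference had 2 (1, 1) at 8 h, 66 (60, 6) at 16 h, 21 (15, 6) at 24 h and 87 (76, 11) in the mean. Resistant against sensitive had 79 (19, 60) at 0 h, 165 (42, 123) over the mean of times and 1700 (184, 1516) within 589bm. Lists with a reversed camera direction had medians of -0.14 for ribosome biogenesis and MYC over the mean of times, and within 589bm -0.76 for glycolysis and -0.41 for plasma cell identity.

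With no filter on dim probes the sensitive response had 0 at 8 h and 2 (2, 0) at 16 h, and the mean over times 0. With the strict filter, which tests fewer probes, the sensitive response had 10 (9, 1) at 8 h and 24 (22, 2) at 24 h, the mean over times 59 (19, 40) and 589bm 42 (2, 40). Lists with a reversed camera direction had medians of -0.0684 for ribosome biogenesis and MYC over the mean of times, and within 589bm -0.37 for glycolysis and -0.26 for plasma cell identity. With the series matrix the sensitive response had 21 (19, 2) at 24 h and the mean over times 0.

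With the 595spVR arrays left out the sensitive response had 177 (123, 54) at 8 h, 1161 (621, 540) at 16 h and 1925 (1032, 893) at 24 h. By construction each resistant time then held a single array, so the near-blank array added nothing to the residuals of this fit. The resistant response had 16256 (6909, 9347) at 2 h and 2 (2, 0) at 24 h, and the response difference 15179 (6602, 8577) at 2 h, where by construction the near-blank array alone stood for the resistant 2 h group. With these arrays grouped by characteristics the sensitive response had 0, 0 and 0 at 8, 16 and 24 h, the resistant response 15053 (6370, 8683) at 2 h and the response difference 13847 (6051, 7796) at 2 h. Here too the near-blank array alone stood for the resistant 2 h group. Resistant against sensitive had 49 (15, 34) at 0 h, 5 (4, 1) over the mean of times and 0 within 595sp. Lists with a reversed camera direction had medians of 0.0849 for S phase within 595sp, -0.0520 for S phase and 0.0560 for ribosome biogenesis and MYC in the resistant response at 16 h, and -0.0607 for ribosome biogenesis and MYC at 24 h.

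With other arrays sharing the spread, the sensitive response had 182 (128, 54) at 8 h, 1158 (617, 541) at 16 h and 1916 (1020, 896) at 24 h, the mean over times 190 (43, 147), 589bm 693 (140, 553) and 595sp 561 (176, 385). For the sensitive response, the spread came from the sensitive arrays alone, so the near-blank array added nothing to it. Lists with a reversed camera direction had medians of -0.0626 for ribosome biogenesis and MYC over the mean of times and -0.37 for glycolysis within 589bm.

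The next settings were chosen after seeing the data. With the near-blank array left out, which removes its spread from the residuals, the sensitive response had 437 (268, 169) at 8 h, 1958 (1022, 936) at 16 h and 2730 (1442, 1288) at 24 h, and the resistant response 39 (26, 13), 247 (126, 121) and 239 (139, 100). The response difference had 8 (2, 6) at 16 h, 6 (0, 6) at 24 h and 16 (1, 15) in the mean, the mean over times 0 and 589bm 3893 (1913, 1980). Lists with a reversed camera direction had medians of 0.28 for ribosome biogenesis and MYC over the mean of times, and within 589bm 0.53 for glycolysis, 0.28 for oxidative phosphorylation and 0.28 for plasma cell identity.

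With that array left out and the series matrix, the sensitive response had 1 (0, 1) at 2 h, 415 (249, 166) at 8 h, 1890 (987, 903) at 16 h and 2656 (1421, 1235) at 24 h, and the resistant response 35 (22, 13), 240 (116, 124) and 230 (124, 106). The response difference had 7 (2, 5) at 16 h, 3 (0, 3) at 24 h and 14 (2, 12) in the mean, the mean over times 0 and 589bm 3845 (1899, 1946). Lists with a reversed camera direction had medians of 0.27 for ribosome biogenesis and MYC over the mean of times, and within 589bm 0.52 for glycolysis, 0.27 for oxidative phosphorylation and 0.16 for plasma cell identity.

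With that array left out and median scaling, the sensitive response had 102 (67, 35) at 8 h, 1292 (156, 1136) at 16 h and 1599 (297, 1302) at 24 h, and the resistant response 5 (3, 2), 19 (14, 5) and 31 (19, 12). The response difference had 5 (2, 3) at 16 h and 7 (2, 5) in the mean, and resistant against sensitive 64 (17, 47) at 0 h, 267 (83, 184) over the mean of times and 4386 (813, 3573) within 589bm. Lists with a reversed camera direction had medians of 0.26 for ribosome biogenesis and MYC over the mean of times, and within 589bm 0.30 for glycolysis, -0.0170 for oxidative phosphorylation and 0.0585 for plasma cell identity.

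With that array and the 595spVR arrays left out, the sensitive response had 181 (127, 54) at 8 h, 1154 (614, 540) at 16 h and 1905 (1012, 893) at 24 h, the resistant response 2 (1, 1) at 16 h and 2 (2, 0) at 24 h, and 589bm 3884 (1918, 1966). Lists with a reversed camera direction within 589bm had medians of 0.53 for glycolysis, 0.28 for oxidative phosphorylation and 0.26 for plasma cell identity.

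Leaving out each of the 20 arrays in turn gave 0 to 0 at 2 h, 0 to 440 at 8 h, 0 to 1978 at 16 h and 0 to 2741 at 24 h in the sensitive response, and 0 to 16485, 0 to 39, 0 to 253 and 0 to 246 in the resistant response. The response difference ran 0 to 15370 at 2 h, 0 to 0 at 8 h, 0 to 8 at 16 h, 0 to 6 at 24 h and 0 to 16 in the mean. Resistant against sensitive ran 0 to 0 at 0 h, where only 16 of the arrays could be left out, 0 to 54 over the mean of times, 0 to 3931 within 589bm and 2887 to 4219 within 595sp. At 2 h the high ends of the resistant response and of the response difference came without the 595sp resistant 2 h array. By construction the near-blank array alone then stood for the resistant 2 h group.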

Other observations

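The tests in this part were chosen after the results were seen, those of a drug response and of a bias of the probes in place of earlier versions, as were the threshold for a shifted chromosome (a median of at least 0.2 in size, beyond all matched random sets) and the use of 5890 brighter genes. Outside the rule for named genes, and chosen after their values were seen, Vpreb1 and Igll1, which encode the surrogate light chain of early B cells, were lower in the resistant 595sp culture by a log2 of -5.35 and -5.18, and Papss2, a sulfate-activating enzyme, by -4.91. Atad1, a mitochondrial ATPase, was higher at 4.23. In 589bm these genes stood at 0.18, 0.47, 0.02 and -0.04. The pairs of cultures of the lines differed for each, against the spread over times (limma interaction, adjusted p = 2.06e-12, 8.01e-11, 3.01e-10 and 1.71e-10).

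Genes on whole chromosomes of the assembly GRCm38.p6 were shifted together between resistant and sensitive cultures. In 595sp, chromosome 4 had a median resistant minus sensitive log2 difference of 0.40 over 394 genes, with 86.5% of them above 0, and chromosome 5 a median of -0.30 over 428 genes, with 19.9% above 0. In 589bm, chromosome 13 stood at 0.39 over 190 genes, with 78.4% above 0, chromosome 14 at 0.23, and chromosomes 3, 15 and 17 at -0.23, -0.24 and -0.23. Chromosome 6 in 595sp had a median of 0.07 in its first part and -0.53 in its second part. In 589bm the shifted chromosomes held 26.3% of the genes that passed, against 21.1% of the 5890 genes used. In 595sp they held 21.5% against 14.0%. What part of the differences of genes and lists named within a line follows these shifts was not tested.

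A drug response of genes on those chromosomes predicts little shift at 0 h, and at least 0.919 of each median over times was present at 0 h. In the first version of this test, which asked that each chromosome's median in the sensitive culture move by less than 0.25 of the shift from 0 to 24 h, this was not met on chromosomes 13 and 14 in 589bm, with moves of 0.13 and 0.06, nor in size on chromosome 3 in 589bm and 5 in 595sp, with moves of 0.09 and 0.13 against the direction of their shifts. A bias that belongs to the probes predicts the same shift in the other line, where the same chromosomes showed at most 0.321 of it. A brightness bias in the arrays of a single line would have to move random sets with the same mean signals, which spanned -0.05 to 0.11 against 0.40 on chromosome 4, but the chromosomes were picked for lying beyond such sets, so it stays open for the smaller shifts. A gain or loss of chromosomes in single cultures predicts a shift along the whole length, and both parts of each chromosome kept at least 0.837 of the median. The chromosomes were picked for their whole median, which left out chromosome 6 in 595sp, shifted in its second part only. This test was therefore unlikely to fail and cannot decide the cause. Copy changes remain possible, while strain variants under the probes were not tested. A change shared by both lines predicts a positive correlation of the 20 chromosome medians, and Pearson r was -0.0869.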
